A study of Rattus norvegicus with 4 samples.

How the data were processed

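The data are 4 single-cell RNA sequencing libraries from Lewis rat liver, 1 library per group, each deposited as a matrix of UMI counts (unique molecular identifiers) per gene and barcode. The groups are an untreated liver (naive), a liver kept for 4 h at 4 °C (CS), a liver perfused for 4 h at 37 °C (NEVLP2) and a liver perfused in the same way with IL-10 and TGF-β (NEVLPcty). The reading of CS as cold storage and of NEVLPcty as perfusion with both cytokines rests on the series description; the labels do not explain the digit in NEVLP2. Per the labels, the perfusate held William's E medium, human albumin, heparin, papaverine, insulin, hydrocortisone and leukoreduced Lewis red cells. The authors state that the study addressed liver-resident T cells; how cells were isolated, and whether any cell type was enriched, is not given in the sources used here. Per the labels, reads were processed with Cell Ranger 2.1.1, whereas the file headers name version 6.0.0; the genome build is not given in the sources used here. Values in the matrices are whole numbers, and nothing upstream of the counts was repeated.

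Each matrix holds 22250 features under 22118 symbols, so 132 features repeat a symbol, and features that share a symbol were summed. The deposited barcodes numbered 3920 in naive, 11200 in CS, 10646 in NEVLP2 and 11763 in NEVLPcty, with 25609611, 67431270, 65893218 and 72271060 UMIs. Median UMIs per barcode were 3482.5, 4465, 3459 and 5313, and median genes 901, 1861, 1270.5 and 1912. Barcodes with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 3301, 10798, 10186 and 11616. The mitochondrial limit was exceeded by 13.9% of naive barcodes, 3.58% in CS, 4.28% in NEVLP2 and 1.11% in NEVLPcty.

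Doublets were called in each library with Scrublet as held in scanpy 1.11.5. It called 8, 331, 210 and 0 barcodes (0.242, 3.07, 2.06 and 0%), at score limits of 0.369, 0.220, 0.267 and 0.646. A call of 0 in 11616 cells is a failed call for NEVLPcty, and the naive call is also low, so doublets remain in both. An added alternative therefore removed the highest scores up to 0.8% of cells per 1000 barcodes in every library, which took 6, 6, 29 and 17 T-like cells. The cells retained were 3293, 10467, 9976 and 11616, in all 35352.

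Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were ranked within each library, and 30 principal components gave the 15 nearest neighbours of each cell. Leiden clustering at resolution 1 with seed 1 returned 35 clusters over the 4 libraries together, with no batch integration. A cluster was named after the leading of 17 cell type lists, by mean log2 fold of its markers over all other cells (0.05 added to each mean). That mean had to reach 0.5, and at least 3 markers had to be detected in more than 10% of the cells. No other list could hold more of the 10 top genes, and a cluster with median UMIs under 1/3 of its libraries' medians needed a marker among them. This named 29 clusters, in 14 classes, and left 6 unnamed. The suffix -like marks such a name, which rests on transcripts only. T-like cells are cluster 14, with 776 cells, which were clustered again into 12 sub-clusters. Proliferating clusters 26, 28 and 33 were left out of the T-like class. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

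Raw counts were summed over the T-like cells of each library and divided by the library's T-like total (3198269, 1017371, 1344947 and 1052982 UMIs in naive, CS, NEVLP2 and NEVLPcty), giving levels in CPM. There are no replicates, so no test, p-value or count of changed genes is given. Intervals are exact 95% limits, conditional binomial for a ratio, Poisson for a level and binomial for a share, and describe counting error only. A gene at 0 counts in 1 library was set to a floor of 3 counts there, and its ratio is given as a minimum. The floor is 0.938, 2.95, 2.23 and 2.85 CPM in the 4 libraries in the same order.

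There were 22 gene lists, fixed beforehand, with 283 genes in those written out by name, of which 9 are not among the features. They are tissue residency, tissue egress and naive, cytotoxicity, cytokines and chemokines, regulatory and inhibitory, immediate early, heat shock, cold-inducible, NF-kB targets, glucocorticoid response, TGF-beta response, IL-10 and STAT3 response, interferon response, glycolysis and hypoxia, unfolded protein and integrated stress, antioxidant, apoptosis and p53, MHC class II, oxidative phosphorylation, cell cycle, ribosomal proteins and mitochondrially encoded genes. For each list the median log2 ratio of CPM was taken over members with at least 10 counts in the 2 libraries together, with an interval from 1000 resamples of the counts. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries only. A list under percentile 2.5 or above 97.5 is called outside the random range. Of 87 list medians, 55 lay outside it. Genes of a random list were drawn independently, whereas genes of a list can vary together, so a list can leave the range more readily. Some genes, such as Nfkbia and Bcl3, are on more than 1 list. Because the random lists carry any shift common to all genes, percentiles and not signs place a list against that shift.

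Named genes are, for each of 4 comparisons, the 10 largest and the 10 smallest ratios among genes with at least 50 CPM in 1 of the 2 libraries and at least 30 counts over both. Symbols that are only identifiers, ribosomal, mitochondrial and immunoglobulin genes, and markers of classes other than T, NK and proliferating cells were left out. Genes whose T-like level was under 10% of the highest class level, called background-prone, were also left out; there were 91, 120, 121 and 142 of these among 2450, 2670, 2774 and 2747 eligible genes in CS against naive, NEVLP2 against naive, NEVLP2 against CS and NEVLPcty against NEVLP2. To these come 2 to 4 members of each list outside the random range, with the most counts or the largest change. Some genes that this rule names are not reported here.

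Shares of cells with a UMI of a gene were taken after each cell was thinned to 2000 UMIs, cells with fewer left out, and the share in hepatocyte-like cells was taken as background. The background level of a gene in the T-like cells was also estimated: for each other class, the median over its markers of the T-like level over the highest cluster level of that class gave a share, which was multiplied by the highest level of the gene in clusters of that class with at least 20 cells and summed over classes, with T, NK and proliferating cells not counted as sources and unnamed clusters taken with the class that leads them. A wider estimate, added after the data were seen, took every cluster but the T-like one with at least 20 cells as a source, its share being the median over its 10 leading genes, those under 50 CPM in it left out.

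The alternatives chosen before the data were examined were a mitochondrial maximum of 10%, at least 500 genes and 1000 UMIs, doublets kept, Leiden resolution 0.5, each library clustered alone, T cells taken by transcripts (a UMI of Cd3e, Cd3d or Cd3g and none of Cd79a, Clec4f or Csf1r), scaling by the median ratio of expressed genes, scaling without ribosomal and mitochondrial genes, cells thinned to 1000 UMIs, list members with at least 50 counts, and background-prone members left out. Those added after the data were seen were doublets removed at the expected rate, T-like cells without sub-clusters in which under 50% of cells held a Cd3 UMI, the same without sub-clusters led by other types, an estimated background subtracted (6.97, 8.92, 11.3 and 11.1% of T-like counts), and T-like cells without the sub-cluster with the most Ifng counts in NEVLP2. A floor that had at first been applied to counts of 1 and 2 as well as to 0 was corrected after results had been seen.

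The code was tested on simulated data, Poisson counts drawn from the mean T-like profile of each pair of libraries with known folds placed in 200 genes. Planted 2-fold changes had the right direction in 96.9% of genes for CS against naive, 98% for NEVLP2 against naive, 96.0% for NEVLP2 against CS and 97.9% for NEVLPcty against NEVLP2, and planted 4-fold changes in 100, 100, 100 and 99.0%. Intervals held the true fold in 97.9, 96, 94.9 and 95.9% at 2-fold and 98.0, 94, 95.8 and 98.0% at 4-fold. They excluded 1 in 61.9, 73, 63.6 and 63.9% at 2-fold and 94.9, 93, 92.7 and 91.8% at 4-fold. Of 200 unchanged lists, 3.5, 4, 3.5 and 3.5% lay outside the random range, and every list with all 14 members raised 2-fold or 4-fold lay above it. The simulated counts were independent between genes and had counting error only. The test therefore does not cover counts held by few cells, genes that vary together, or lists whose members go both ways.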

Results

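Livers of Lewis rats were profiled by single-cell RNA sequencing after 4 treatments: none (naive), 4 h at 4 °C (CS), 4 h of perfusion at 37 °C (NEVLP2) and perfusion with IL-10 and TGF-β (NEVLPcty). After filtering, 3293, 10467, 9976 and 11616 cells were retained. Each treatment is represented by 1 library, so a difference between libraries cannot be assigned to treatment rather than to the animal or the preparation.

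T-like cells, in 1 cluster marked by Cd3e, Cd3d, Cd3g, Lck and Bcl11b, made up 9.44% of retained naive cells (95% interval 8.47 to 10.5%). They were 1.60% in CS (1.36 to 1.85%), 1.74% in NEVLP2 (1.5 to 2.02%) and 1.07% in NEVLPcty (0.889 to 1.27%), which is 311, 167, 174 and 124 cells. Non-immune cells differed too, and endothelial-like cells were 0.850% of naive, 38.2% of CS, 4.88% of NEVLP2 and 53.5% of NEVLPcty cells, and hepatocyte-like cells 32.1, 9.32, 9.65 and 6.71%. Among immune-like cells the T-like share was 20% in naive, 6% in CS, 5.18% in NEVLP2 and 5.96% in NEVLPcty. The T-like share moved by more than 1.5 times where T cells were taken by transcripts, to 4.63% in NEVLP2, 2.5% in CS and 1.76% in NEVLPcty. Only 132 of 462, 101 of 262 and 101 of 205 of the cells so taken were T-like in the main analysis.

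Within the T-like, NK-like and B-like cells together, NK-like cells were the larger part after perfusion: 28.1% in naive, 38.4% in CS, 61.1% in NEVLP2 and 75.4% in NEVLPcty. T-like cells were 50.2, 19.3, 24.2 and 17.2% and B-like cells 21.8, 42.3, 14.6 and 7.47%. Of all retained cells, NK-like cells differed less (5.28, 3.18, 4.40 and 4.69%) than B-like cells (4.10, 3.51, 1.05 and 0.465%). Monocyte or macrophage-like cells were 12.2% in naive and 7.54% in NEVLP2, against 1.92% in CS and 1.57% in NEVLPcty. Kupffer-like cells were 5.38, 10.8, 7.99 and 4.64%, conventional dendritic-like cells 5.92, 3.45, 5.41 and 4.74%, and plasmacytoid dendritic-like cells 2.52, 1.97, 3.37 and 0.620%. Stellate or fibroblast-like cells were 0.213, 2.51, 4.29 and 9.48%. Clusters without a name held 15.9, 22.3, 46.7 and 11.8% of cells, with median UMIs of 1314.5, 1072, 1850 and 1914. Hepatocyte markers led unnamed clusters 2 (25.7% of NEVLP2 cells) and 4 (14.7% of naive and 12.8% of CS cells). Endothelial markers led unnamed clusters 5 (18.2% of NEVLP2 cells, at a mean log2 fold of only -0.08) and 12 (9.31% of CS cells). The hepatocyte-like and endothelial-like shares may therefore leave out cells of these types. The proliferating clusters, which carry Mki67 and Top2a and were not counted as T-like, held 1.40, 0.344, 0.0401 and 0.284% (cluster 26), 0.516, 0.306, 0.271 and 0.112% (cluster 28) and 0.425, 0.220, 0.1 and 0.0603% (cluster 33).

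**Figure D1:**
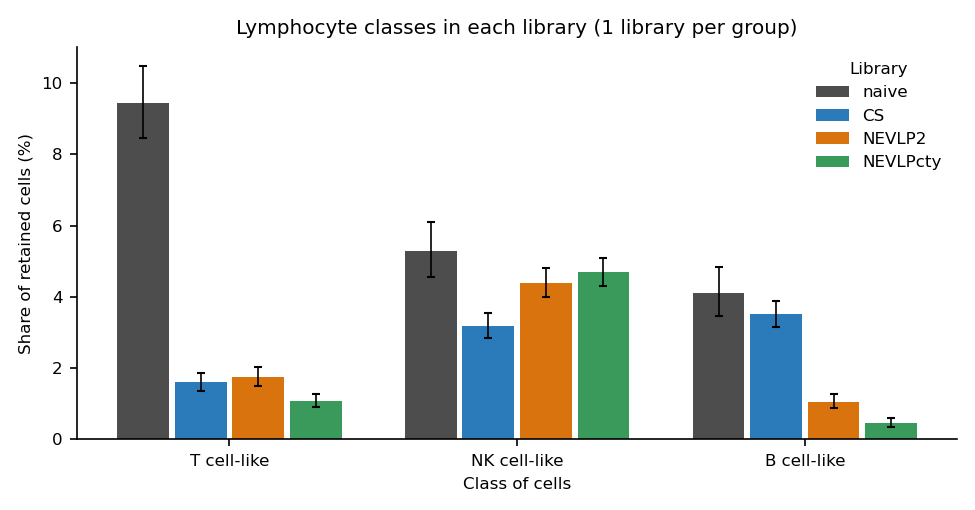
Share of retained cells (%, vertical axis) that are T-like, NK-like and B-like in the naive, CS, NEVLP2 and NEVLPcty libraries, with exact 95% binomial intervals. T-like cells were 9.44, 1.60, 1.74 and 1.07%.

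Fewer T-like cells of the perfused livers than of the others held transcripts of Lef1 and S1pr1. Lef1, a transcription factor of naive and memory T cells, was found in 57.0% of naive and 43.1% of CS T-like cells after thinning to 2000 UMIs, against 7.14% in NEVLP2 and 16.5% in NEVLPcty; without thinning these shares were 80.1, 61.1, 20.1 and 30.6%. Cxcr3, a receptor of effector T cells, went the other way, at 10.5, 9.15, 28.0 and 27.3% (unthinned 23.2, 21.0, 50 and 47.6%). Il2ra was found in 4.92, 7.84, 22.6 and 19.8% (unthinned 17, 13.8, 48.3 and 30.6%). Cd69 was found in 27.9, 27.5, 35.1 and 14% (unthinned 65.6, 52.7, 58.6 and 36.3%), and Cxcr6 in 3.61, 6.54, 5.95 and 9.92% (unthinned 9.32, 11.4, 23.0 and 32.3%). Hepatocyte-like cells, taken as background, held Lef1, Cxcr3, Il2ra, Cd69 and Cxcr6 each in at most 0.867% of cells after thinning. Itgae was found in 5.90, 3.27, 2.38 and 6.61% of T-like cells (unthinned 21.2, 10.2, 10.3 and 14.5%) against 1.04, 0.885, 0.983 and 4.78% of hepatocyte-like cells, so in NEVLPcty it was close to background. S1pr1, an egress receptor, was found in 37.7, 31.4, 10.1 and 19.0% (unthinned 73.3, 51.5, 24.7 and 44.4%), against 1.91, 1.99, 2.95 and 1.95% of hepatocyte-like cells. Median UMIs were 9328, 6042, 7056 and 7404 in T-like and 2176, 1903.5, 2909 and 2865 in hepatocyte-like cells, and thinning left out 6, 14, 6 and 3 T-like and 480, 524, 251 and 214 hepatocyte-like cells.

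The T-like class was made up differently in each library. Of its 12 sub-clusters, sub-cluster 0 held 147 of 311 naive cells and sub-cluster 1 held 70 of 167 CS cells, whereas sub-clusters 3 and 5 held 50 and 53 of 174 NEVLP2 cells and sub-clusters 3 and 6 held 42 and 23 of 124 NEVLPcty cells. Sub-cluster 2, with Cd8a and killer cell lectin-like receptor genes, had at least 20 cells in every library (40, 20, 23 and 20) and allows a comparison within 1 group of cells. A Cd3 UMI was present in 96.1, 88.0, 89.1 and 87.1% of T-like cells. Sub-clusters 8 and 9, where only 3.33 and 4% of cells had one, held 10, 16, 18 and 11 cells. Sub-cluster 10, led by endothelial genes, held 11 NEVLPcty cells and at most 2 in any other library.

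**Figure D2:**
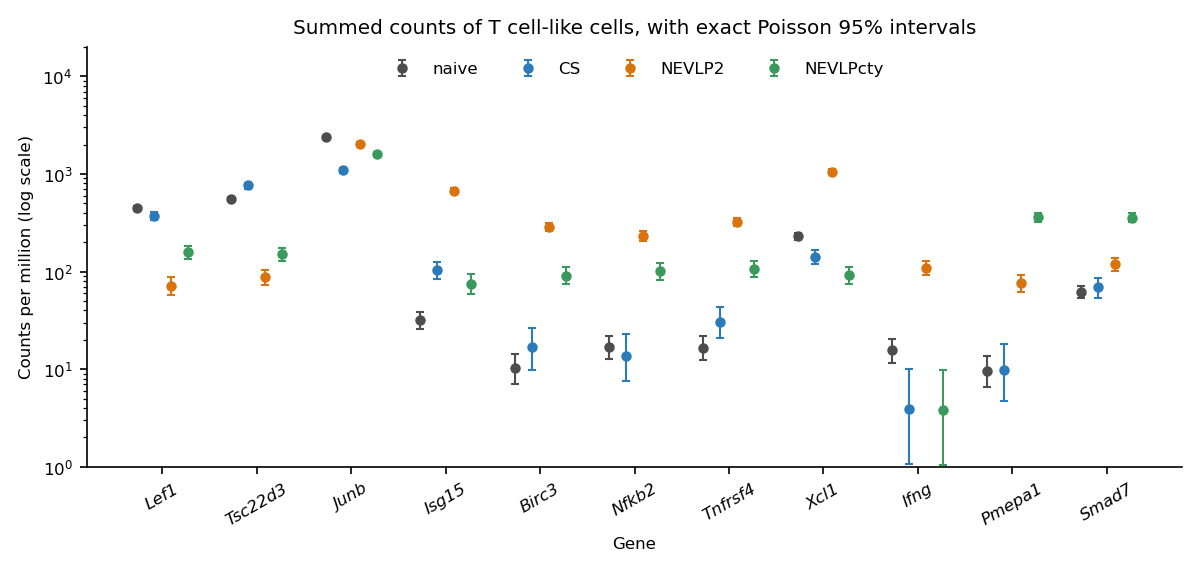
Level in T-like cells (CPM, logarithmic vertical axis) of 11 genes in the naive, CS, NEVLP2 and NEVLPcty libraries, with exact 95% Poisson intervals. Lef1 was at 447, 371, 71.4 and 159 and Pmepa1 at 9.69, 9.83, 75.8 and 359.

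Cold-stored against naive T-like cells showed higher interferon-response transcripts. Cytokine, immediate early and unfolded protein transcripts were lower in the main analysis, but each of these 3 lists changed sign under at least 1 alternative. The cytokine and unfolded protein lists lay below the random range within each of sub-clusters 1, 2 and 4. Isg15 was 3.24-fold (2.44 to 4.29) higher in CS, Mx2 2.53-fold (1.63 to 3.89) and Rtp4 2.17-fold (1.49 to 3.14). After thinning to 2000 UMIs, Isg15 was found in 4.26% of naive and 11.1% of CS T-like cells. Hepatocyte-like cells held it in 2.25 and 11.5%, so in CS the T-like share was no higher than theirs. Whether hepatocyte-like cells held it as free RNA or as their own transcripts was not tested, so their share may not be background for this gene. Hepatocyte markers in CS T-like cells stood at 0.249% of their hepatocyte level. Sub-cluster 4, with 31 CS cells, held 48.6% of the CS counts of Isg15. Junb, the immediate early gene with the most counts, was 2.21-fold (2.07 to 2.35) lower, and Ifng was 3.98-fold (1.46 to 15.2) lower, with 4 and 50 counts. The tissue residency list did not separate the libraries, at a median log2 ratio of 0.28 (-0.01 to 0.46) and percentile 76.1 of random lists, or 0.59 with each library clustered alone; within sub-cluster 1 it was lower in CS, at -0.65 (-1.29 to -0.04) and percentile 0.42.

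The interferon response list had a median log2 ratio of 1.00 (0.71 to 1.26), above all random lists, with 10 of 19 members at least 2-fold higher in CS and 0 lower. Irf7 and Ifi27 were higher by 3.14-fold (2.08 to 4.75) and 2.94-fold (2.37 to 3.64) and Ifit3 by 15.7-fold (6.44 to 46.2), all 3 background-prone, while Mx1 differed by 1.21-fold (1.01 to 1.44). Within sub-cluster 2 the median was 0.73 (0.04 to 0.98) and within sub-cluster 4, which includes the Foxp3 cells, 1.13 (0.80 to 1.38). Within sub-cluster 1, the shared group with the most cells (70 in CS and 43 in naive), it was 0.45 (0.23 to 1.41), within the random range. Ddit4, an inhibitor of mTOR signalling, was 4.2-fold (3.49 to 5.06) higher in CS.

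The immediate early list had a median of -0.28 (-0.43 to -0.13), at percentile 0.01. Nr4a2 was 2.52-fold (1.44 to 4.76) lower and Jund 1.29-fold (1.17 to 1.42) lower, while Btg2 was level (1.01-fold) and the background-prone Ier3 was 7.47-fold (4.07 to 14.3) higher. The sign of this list depends on how T cells are chosen. Its median was 0.20 with doublets kept, 0.03 with each library clustered alone and 0.06 with T cells taken by transcripts. The median over all genes was 0.18 in the main analysis, so a value above 0 need not mean a rise against other genes. Within sub-cluster 2 it was -0.73 (-1.04 to -0.55) and within sub-cluster 4 -0.57 (-0.92 to -0.31), but within sub-cluster 1 it was 0.05 (-0.24 to 0.48), within the random range. Junb is an AP-1 subunit and Nr4a2 an orphan nuclear receptor, both induced within minutes to hours of stimulation.

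Cytokine and chemokine genes had a median of -0.71 (-1.04 to -0.54), at percentile 0.04. Ccl4 was 1.92-fold (1.75 to 2.1) lower in CS, Ccl3 1.47-fold (1.34 to 1.62) and Xcl1 1.63-fold (1.36 to 1.96). Il17a had 272 counts from 7 naive cells and 0 in CS, at least 28.8-fold lower. The median turned to 0.14 with each library clustered alone, a value still under the main median over all genes, 0.18. Within sub-clusters 1, 2 and 4 it lay below the random range. It was -3.49 (-4.03 to -3.06), -0.94 (-1.26 to -0.65) and -4.30 (-4.42 to -2.62) there, over only 2, 5 and 4 measured members.

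Unfolded protein and integrated stress genes had a median of -0.39 (-0.68 to -0.25), at percentile 0.02, which turned to 0.34 with T cells taken by transcripts. Within sub-clusters 1, 2 and 4 it was -0.68 (-0.89 to -0.11), -0.62 (-1.17 to -0.33) and -0.43 (-0.86 to -0.24), each below the random range. Dnajb9, an endoplasmic reticulum co-chaperone, was 2.79-fold (2 to 3.99) lower in CS (0.23 in log2 by transcripts), Hspa5 1.62-fold (1.45 to 1.83), Atf4 1.51-fold (1.33 to 1.73) and Ddit3 1.82-fold (1.32 to 2.55). In the heat shock list, at -0.19 (-0.33 to -0.02) and percentile 0.22, Hspe1 was 1.95-fold (1.65 to 2.31) lower and Hspa8 1.25-fold (1.16 to 1.34) lower, with Hsp90ab1 level (1.01-fold). Other genes with the smallest ratios were Tmem258b (5.15-fold, 2.81 to 10.5, lower in CS), Tra2a (3.73-fold, 2.5 to 5.80), Rgs2 (3.28-fold, 2.37 to 4.67), Mrpl33 (3.05-fold, 2.20 to 4.34), Tomm6 (2.97-fold, 2.12 to 4.27), Cox14 (2.64-fold, 1.96 to 3.63), Malt1 (2.58-fold, 1.91 to 3.56) and Snrpg (2.41-fold, 1.70 to 3.49). Malt1 encodes the paracaspase that links the antigen receptor to NF-kB.

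Most genes with the largest CS ratios came from sub-cluster 8, which is low in Cd3 and led by the basophil and mast cell genes Hdc and Gata2. All 122 CS counts of Dnase2b and all 52 of Pla2g7 lay there, in 7 cells each, at 192-fold (52.0 to 1601) and 54.5-fold (17.6 to 273) higher. It also led Cd63 (11.8-fold, 8.05 to 17.6), Enpp3 (8.17-fold, 5.08 to 13.5), Ncf1 (4.88-fold, 3.19 to 7.54), Plek (4.05-fold, 2.78 to 5.94), Lta4h (4.01-fold, 2.73 to 5.90) and Ctsd (3.39-fold, 2.68 to 4.29). The log2 ratio of Enpp3 turned to -0.60 without sub-clusters low in Cd3 and to -1.23 by transcripts, that of Ncf1 to -0.09 at a 10% mitochondrial maximum and that of Pla2g7 to -0.01 by transcripts.

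Genes of recirculating T cells went both ways in CS against naive. The egress list had a median of -0.20 (-0.35 to 0.08), at percentile 1.15, below the random range; S1pr1 was 1.79-fold (1.5 to 2.13) lower and Lef1 1.21-fold (1.08 to 1.36) lower, whereas Il7r was 1.78-fold (1.41 to 2.23) higher and Tcf7 1.51-fold (1.17 to 1.94) higher. Within sub-cluster 1 the egress median was above the random range, at 0.62 (0.05 to 0.84) and percentile 99.6, and within sub-clusters 2 and 4 it lay within it, at -0.31 (-0.82 to 0.06) and -0.24 (-0.55 to 0.17). MHC class II genes were lower in CS, at -1.54 (-1.71 to -1.40) and below all random lists, with Cd74 at 2.91-fold (2.54 to 3.35) lower and RT1-Bb at 4.69-fold (3.68 to 6.06) lower. All are background-prone, 86 to 91% of their naive counts came from sub-cluster 4 and up to 47% from 1 cell, and the median turned to 1.45 by transcripts. Mitochondrially encoded genes had a median of -0.22 (-0.31 to -0.17) and ribosomal protein genes -0.11 (-0.18 to -0.10), both outside the random range; Mt-nd3 was 3.10-fold (2.64 to 3.67) lower and Mt-atp8 2.95-fold (2.15 to 4.16) lower. Within the random range lay the mitochondrially encoded list in sub-clusters 1, 2 and 4, MHC class II in sub-clusters 1 and 2 and heat shock in sub-cluster 4. Across all 9207 genes the median log2 ratio was 0.18, and the sign of a list median is to be read against it.

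The remaining lists lay within the random range in CS against naive: TGF-beta response (0.42, 0.17 to 0.62), glucocorticoid response (0.32, -0.15 to 0.51), antioxidant (0.32, 0.10 to 0.52), cytotoxicity (0.20, 0.05 to 0.29), NF-kB targets (0.17, -0.24 to 0.37), cold-inducible (0.16, -0.02 to 0.34), IL-10 and STAT3 response (0.12, -0.13 to 0.40), glycolysis and hypoxia (0.07, -0.25 to 0.23), regulatory and inhibitory (-0.02, -0.29 to 0.30), apoptosis and p53 (-0.04, -0.25 to 0.26), oxidative phosphorylation (-0.05, -0.14 to 0.01) and cell cycle (-0.82, -1.46 to 0.09). Within sub-cluster 1, however, the cytotoxicity list was at -1.15 (-1.85 to -0.49) and the regulatory list at -1.01 (-1.55 to -0.33), both below the random range, as were the apoptosis (-0.41, -0.94 to 0.12) and glucocorticoid response lists (-0.20, -0.59 to 0.49) there. The glucocorticoid list went the other way within sub-cluster 4, at 0.74 (0.08 to 1.21) and above the range, while oxidative phosphorylation (-0.40, -0.55 to -0.23) and NF-kB targets (-0.36, -1.17 to -0.02) lay below it there. The TGF-beta list lay above it within sub-cluster 2 (0.70, -0.13 to 1.10). Of the cold-inducible pair, Rbm3 was 1.32-fold (1.21 to 1.43) higher in CS and Cirbp 1.05-fold (0.833 to 1.35) lower.

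Perfused (NEVLP2) against naive T-like cells carried more NF-kB target, interferon, cytotoxicity and residency transcripts and fewer transcripts of recirculation genes. Birc3 was 27.8-fold (19.5 to 41.0) higher, Isg15 21.2-fold (17.3 to 26.3) higher and Runx3 6.67-fold (5.21 to 8.61) higher, while Lef1 was 6.27-fold (5.10 to 7.79) lower. The immediate early list, in contrast, had a median of -0.38 (-0.50 to -0.10), at percentile 0.43, with Jun 1.71-fold (1.56 to 1.89) lower and Dusp2 2.84-fold (2.58 to 3.14) higher. Its median was 0.00 both with cells thinned to 1000 UMIs and with each library clustered alone, and within sub-cluster 2 it was -0.63 (-0.85 to -0.13), below the random range.

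NF-kB targets had a median of 2.42 (2.24 to 2.77), with 12 of 14 members at least 2-fold higher in NEVLP2. Bcl3, which binds the p50 and p52 subunits, was 29.7-fold (17.9 to 53) higher, Nfkb2 13.7-fold (10.2 to 18.6), Traf1 12.4-fold (10.5 to 14.8), Nfkb1 5.25-fold (4.52 to 6.11) and the inhibitor gene Nfkbia 2.58-fold (2.43 to 2.74). Tnfrsf4, which encodes OX40, was 19.5-fold (14.6 to 26.4) higher, mostly in sub-cluster 3, and Il2ra 6.98-fold (5.59 to 8.77) higher. Within sub-cluster 2 the NF-kB median was 3.34 (2.43 to 3.95).

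The interferon response list had a median of 2.19 (1.90 to 2.42), with 17 of 19 members at least 2-fold higher. Rtp4 was 8.23-fold (6.33 to 10.8) higher, Irf1 3.27-fold (2.84 to 3.78) and Bst2 2.07-fold (1.79 to 2.38), while Mx1 was 1.71-fold (1.39 to 2.13) lower. Ubd, an inflammation-induced ubiquitin-like modifier, was 26.2-fold (21.8 to 31.7) higher, although 92% of its naive counts were in 1 cell. Casp4, the inflammatory caspase, was 15.1-fold (10.2 to 22.9) higher and Gfi1 14.1-fold (8.76 to 24) higher.

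Cytotoxicity genes had a median of 2.41 (2.29 to 2.72), with 9 of 11 members at least 2-fold higher. Gzmk was 9.37-fold (8.25 to 10.7) higher, Ccl5 6.55-fold (6.26 to 6.86), Nkg7 5.31-fold (4.83 to 5.84) and the background-prone Gzmb 103-fold (61.1 to 190), and sub-cluster 5 held 86% of Gzmk and 87% of Ccl5 counts in NEVLP2. Within sub-cluster 2 the median was 1.56 (1.36 to 1.76). Of the cytokine list, at 1.21 (0.67 to 1.66), Ifng was 7.04-fold (5.08 to 9.90) higher and Xcl1 4.63-fold (4.23 to 5.06) higher, while Il17a was 2.54-fold (1.85 to 3.57) lower. Ccl1 was 267-fold (90.6 to 1302) higher, with 92% of its counts in 1 cell.

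Tissue residency genes had a median of 1.58 (1.15 to 1.82), with 7 of 12 members at least 2-fold higher; Cxcr3 was 4.81-fold (4.06 to 5.72) higher, Rgs1 1.89-fold (1.72 to 2.07) and Cd69 1.76-fold (1.57 to 1.98). Egress genes had a median of -2.29 (-2.55 to -1.66), below all random lists, with S1pr1 4.36-fold (3.49 to 5.51) lower and Klf2 12.2-fold (4.64 to 45.5) lower. The naive counts of Lef1, S1pr1 and Klf2 lay mostly in sub-cluster 0, which had 1 cell in NEVLP2. Within sub-cluster 2 the egress median was -0.37 (-1.18 to -0.04), within the random range, and the residency median 0.97 (0.66 to 1.29).

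Among glucocorticoid response genes, at 0.10 (-0.17 to 0.58) and within the random range, Tsc22d3 was 6.34-fold (5.26 to 7.70) lower and Klf9 6.10-fold (4.19 to 9.23) lower in NEVLP2, the 2 among the smallest ratios of all genes. Of 13 measured members, 4 were at least 2-fold lower and 4 at least 2-fold higher. Within sub-cluster 2 the list was at -0.67 (-1.32 to -0.36), below the random range. Hydrocortisone was part of the perfusate, and Tsc22d3 and Klf9 are glucocorticoid receptor targets. Other genes with the smallest ratios were Pcbd2 (14.4-fold, 6.52 to 39.8, lower), Bicdl1 (8.94-fold, 5.03 to 17.5), Ramp1 (8.56-fold, 6.30 to 11.9), Rasa3 (7.31-fold, 4.42 to 13.0), Tmem258b (6.80-fold, 3.71 to 13.9) and Rab3ip (6.14-fold, 4.55 to 8.47).

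Apoptosis, glycolysis and antioxidant lists were also higher in NEVLP2. Fas was 15.8-fold (9.27 to 28.6) higher and Gadd45b 9.42-fold (7.86 to 11.3), in an apoptosis and p53 list at 1.18 (0.83 to 1.70). Aldoa was 4.39-fold (4.05 to 4.76) higher and Ldha 3.33-fold (3.12 to 3.55), in a glycolysis and hypoxia list at 1.03 (0.88 to 1.34). The antioxidant list was at 1.11 (0.85 to 1.27), with Prdx1 2.15-fold (1.93 to 2.40) higher and the background-prone Hmox1, with 275 and 2 counts, 327-fold (89.7 to 2713) higher; its median turned to -0.88 after an estimated background was subtracted. Stat3 was 5.26-fold (4.46 to 6.21) higher in the IL-10 and STAT3 list (1.12, 0.66 to 1.56), Pmepa1 7.82-fold (5.19 to 12.1) and Skil 6.56-fold (4.78 to 9.13) higher in the TGF-beta list (0.96, 0.76 to 1.44), and Tnfrsf18 5.22-fold (4.55 to 5.99) and Tgfb1 3.08-fold (2.74 to 3.46) higher in the regulatory and inhibitory list (0.85, 0.41 to 1.09), which turned to -0.03 by transcripts. The glycolysis list within sub-cluster 2 was at 0.69 (0.32 to 0.94), outside the random range, whereas the apoptosis (0.16, -0.20 to 0.96), cytokine (0.76, 0.04 to 1.58), TGF-beta (0.60, 0.00 to 1.21) and regulatory lists (0.32, -0.38 to 0.99) lay within it.

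Cirbp was 5.34-fold (3.52 to 8.47) lower in NEVLP2 and Rbm3 1.45-fold (1.34 to 1.56) higher, for a cold-inducible median of -0.94 (-1.27 to -0.67). Mitochondrially encoded genes (-0.76, -0.79 to -0.70) and ribosomal protein genes (-0.40, -0.43 to -0.29) were lower, with Mt-co3 at 1.44-fold (1.41 to 1.47) and Mt-nd3 at 5.25-fold (4.38 to 6.33) lower. Heat shock (0.51, 0.39 to 0.62), unfolded protein (0.46, 0.27 to 0.68), MHC class II (0.03, -0.11 to 0.13), oxidative phosphorylation (0.05, -0.07 to 0.12) and cell cycle genes (-0.11, -0.78 to 0.56) lay within the random range. In sub-cluster 2 alone, however, MHC class II was at 1.57 (0.94 to 2.06), above that range, and the cold-inducible pair at -0.27 (-1.22 to 0.28), within it. Across all 9281 genes the median log2 ratio was 0.10.

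Perfused (NEVLP2) against cold-stored T-like cells had higher NF-kB target, residency and cytotoxicity transcripts and lower egress transcripts; the same NEVLP2 library also enters the comparison with naive, so the 2 comparisons are not independent. The NF-kB target median was 2.67 (2.16 to 3.23), with 13 of 14 members at least 2-fold higher: Birc3 17.2-fold (10.6 to 29.8), Nfkb2 16.8-fold (9.86 to 31.1), Bcl3 13.8-fold (7.52 to 28.0), Traf1 11.3-fold (8.60 to 15.0) and Nfkbia 3.13-fold (2.85 to 3.45). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was 35.1-fold (17.6 to 81.9) higher. Lef1 was 5.19-fold (4.14 to 6.57) lower and Klf2 13.6-fold (4.91 to 52.1) lower in NEVLP2, in an egress list at -1.78 (-2.01 to -1.05). In sub-cluster 2 alone the egress median was -0.35 (-1.25 to 0.46), within the random range.

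The tissue residency median was 1.03 (0.71 to 1.51), at percentile 100, with 6 of 12 members at least 2-fold higher in NEVLP2 and a value of 0.49 with T cells taken by transcripts. Xcl1 was 7.54-fold (6.35 to 9.02) higher, Rgs1 3.76-fold (3.19 to 4.47), Runx3 3.59-fold (2.66 to 4.94), Cxcr3 3.29-fold (2.63 to 4.15) and Cd69 1.53-fold (1.31 to 1.79). Itgae and Cxcr6, chosen after their values were seen because they mark liver-resident T cells, were 1.45-fold (0.766 to 2.75) lower and 1.86-fold (1.19 to 3) higher. Within sub-cluster 2 the residency median was 0.98 (0.57 to 1.45).

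The cytotoxicity median was 1.78 (1.61 to 1.97), above all random lists. Ccl5 was 12.5-fold (11.3 to 13.8) higher, Gzmk 10.4-fold (8.32 to 13.1), Nkg7 5.25-fold (4.53 to 6.11) and the background-prone Gzmb 76.7-fold (35.0 to 210). Sub-cluster 5, with 53 NEVLP2 cells and 0 in CS, held 71% of the NEVLP2 counts of Ifng and most of those of Gzmk; without it the median was 0.96. Within sub-cluster 2 it was 1.56 (1.26 to 1.84). Ifng was 28.0-fold (10.7 to 104) higher in NEVLP2, Ccl4 2.33-fold (2.12 to 2.57) higher (background-prone) and Lta 2.09-fold (1.48 to 2.99) higher, in a cytokine list at 2.60 (1.92 to 2.98). Il17a had 45 counts in NEVLP2 and 0 in CS, at least 11.3-fold higher.

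The glucocorticoid response list did not separate NEVLP2 from CS, at -0.06 (-0.28 to 0.16) and percentile 23.1, with hydrocortisone in the perfusate of NEVLP2. Its members went both ways: Tsc22d3 was 8.69-fold (7.15 to 10.6) lower and Nfkbia, which is also on the NF-kB target list, higher. With doublets kept the median was -0.39 and with T cells taken by transcripts -0.62.

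Interferon response genes had a median of 1.15 (0.70 to 1.32), with Isg15 6.56-fold (5.35 to 8.10) higher, Gbp5 5.95-fold (4.45 to 8.10) and Irf1 2.81-fold (2.30 to 3.45), all 3 inducible by IFN-γ. Ubd was 115-fold (60.2 to 251) higher. In the apoptosis and p53 list, at 1.05 (0.69 to 1.53), Gadd45b was 12.5-fold (8.91 to 18.0) higher. In the glycolysis list, at 1.10 (0.92 to 1.47), Aldoa was 3.87-fold (3.43 to 4.36) and Gapdh 2.76-fold (2.51 to 3.04) higher. Unfolded protein genes had a median of 0.83 (0.62 to 1.19), with Calr 3.02-fold (2.68 to 3.41) and Atf4 2.70-fold (2.36 to 3.10) higher, and heat shock genes 0.61 (0.44 to 0.75), with Dnaja1 3-fold (2.57 to 3.52) and Hspa8 2.11-fold (1.96 to 2.28) higher. Stat3 was 3.73-fold (2.99 to 4.69) higher in the IL-10 and STAT3 list (1.28, 0.47 to 1.92), and Il2ra 4.75-fold (3.52 to 6.54) and Tnfrsf18 3.96-fold (3.28 to 4.82) higher in the regulatory list (1.04, 0.67 to 1.33). In sub-cluster 2 the apoptosis (1.89, 1.49 to 2.5), glycolysis (0.95, 0.65 to 1.24), interferon (1.07, 0.56 to 1.75) and unfolded protein lists (1.28, 1.03 to 1.86) stayed outside the random range, whereas the heat shock (0.34, 0.16 to 0.75), IL-10 and STAT3 (0.67, 0.12 to 1.20) and regulatory lists (0.87, 0.55 to 1.42) lay within it.

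Cks2, a partner of cyclin-dependent kinases, was 39.1-fold (20.4 to 86.0) higher in NEVLP2, although Mki67 was the only cell cycle member measured. Mxd1, a MAX partner that opposes MYC, was 16.3-fold (8.41 to 36.2) higher and the zinc transporter gene Slc39a10 14.1-fold (7.26 to 31.4). Ccl1, with 337 and 0 counts, was at least 85-fold higher, again mostly from 1 cell. The smallest ratios were those of Dnase2b (53.8-fold, 18.0 to 264, lower, from sub-cluster 8 in CS), Cdca7l (11.7-fold, 5.02 to 33.2), Rasa3 (10.8-fold, 6.42 to 19.5), Ramp1 (8.82-fold, 6.39 to 12.5), Rab3ip (7.44-fold, 5.42 to 10.4), Atp2a3 (7.42-fold, 4.08 to 14.6), Bicdl1 (7.38-fold, 3.96 to 15.0), Add3 (6.90-fold, 5.08 to 9.54) and Sytl1 (6.85-fold, 4.31 to 11.4). Cirbp was 5.07-fold (3.20 to 8.31) lower and Rbm3 level (1.10-fold), for a cold-inducible median of -1.10 (-1.48 to -0.79).

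The antioxidant list was at 0.87 (0.73 to 0.97), with the background-prone Hmox1 23.1-fold (12.0 to 51.1) and Prdx1 1.83-fold (1.58 to 2.11) higher; it turned to -0.79 after background subtraction. MHC class II genes, all background-prone, were at 1.61 (1.40 to 1.82), with Cd74 4.88-fold (4.24 to 5.63) higher. Mitochondrially encoded genes were at -0.54 (-0.56 to -0.48), with Mt-nd3 1.69-fold (1.33 to 2.15) lower, and ribosomal protein genes at -0.23 (-0.25 to -0.21). Within the random range were TGF-beta response (0.39, 0.01 to 0.85), immediate early (-0.02, -0.21 to 0.27) and oxidative phosphorylation genes (0.06, -0.03 to 0.16). In sub-cluster 2 alone the immediate early list was at 0.62 (0.33 to 1.26), above the random range, whereas antioxidant (0.60, 0.33 to 0.96), MHC class II (0.89, 0.40 to 2.04), ribosomal protein (-0.12, -0.15 to -0.08) and cold-inducible genes (-0.32, -1.20 to 0.46) lay within it.

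**Figure D3:**
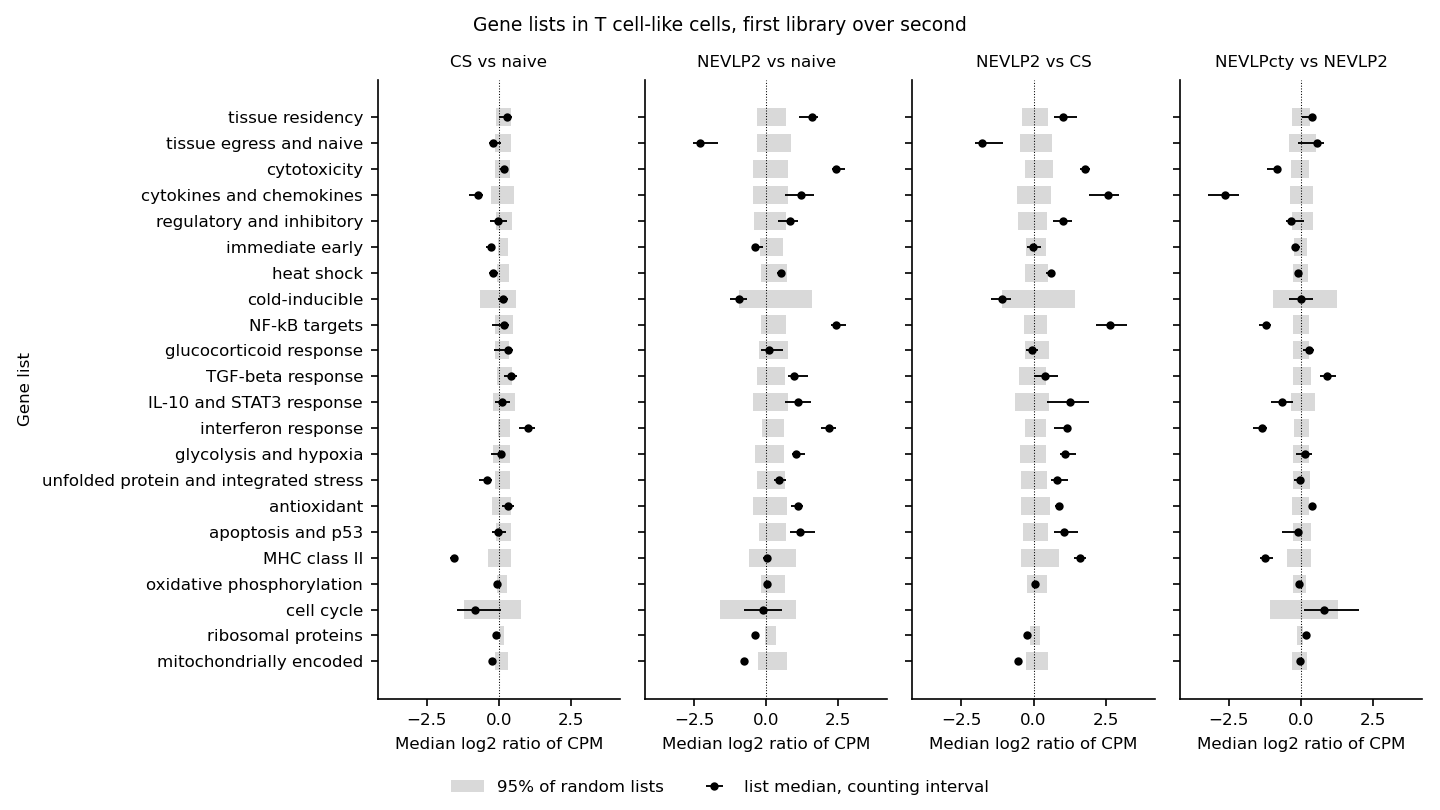
Median log2 ratio (horizontal axis) in T-like cells of 22 gene lists in 4 comparisons of the naive, CS, NEVLP2 and NEVLPcty libraries, with counting intervals and the central 95% of random lists in grey. NF-kB targets were at 2.67 in NEVLP2 against CS and TGF-beta response genes at 0.91 in NEVLPcty against NEVLP2.

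With IL-10 and TGF-β in the perfusate (NEVLPcty against NEVLP2), T-like cells had higher transcripts of TGF-beta targets and lower transcripts of NF-kB targets, interferon response genes and cytokines. Pmepa1 was 4.73-fold (3.79 to 5.95) higher and Smad7, the inhibitory SMAD, 2.99-fold (2.48 to 3.63) higher, both SMAD targets that limit the pathway. Ifng was 29.0-fold (11.1 to 108) lower, Xcl1 11.5-fold (9.37 to 14.3) lower and Isg15 9.02-fold (7.16 to 11.5) lower. The IL-10 and STAT3 response list was lower, at -0.65 (-1.04 to -0.28).

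The TGF-beta response list had a median of 0.91 (0.65 to 1.23), above all random lists, and between 0.76 and 1.03 under every alternative. Endothelial markers in T-like cells stood at 5.85% of their endothelial level in NEVLPcty against 0.375% in NEVLP2, and stellate markers at 4.27% of theirs against 0.722%. The NEVLPcty T-like levels of Pmepa1 and Smad7 were 118 and 82.0% of the highest level in any other class, that of NK-like cells. Ldlrad4 was 3.01-fold (2.13 to 4.31) higher and Ski 4.26-fold (1.65 to 13.0) higher, with 20 and 6 counts, whereas Id2 was 2.35-fold (2 to 2.76) lower. Within sub-cluster 3 the median was 0.98 (0.49 to 1.36) and within sub-cluster 2 1.53 (0.87 to 2.08).

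The IL-10 and STAT3 list lay at percentile 0.065, with Bcl3 2.75-fold (2.04 to 3.76) lower, Pim1 2.24-fold (1.36 to 3.83) lower, Stat3 1.30-fold (1.12 to 1.52) lower and Il4r 1.91-fold (1.47 to 2.49) higher. Bcl3 is also on the NF-kB target list. Socs3, a direct STAT3 target chosen after its value was seen, was 1.14-fold (0.496 to 2.71) lower. At least 2-fold lower were 3 of 11 members, and 0 were as much higher. Within sub-cluster 3 the median was -0.70 (-1.31 to -0.45) and within sub-cluster 2 -0.27 (-0.78 to 0.75), within the random range. With cells thinned to 1000 UMIs the median was -1.18.

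The tissue residency median was 0.38 (0.03 to 0.50), at percentile 99.3, and turned to -0.64 with cells thinned to 1000 UMIs. Its members went both ways: Cd69 was 2.77-fold (2.30 to 3.37) lower and Cxcr3 1.62-fold (1.36 to 1.92) lower, while Rgs1 was 1.39-fold (1.26 to 1.52) higher and Itgae, with 29 and 21 counts, 1.76-fold (0.972 to 3.25) higher. Itga1, 4.77-fold (2.66 to 9.08) higher, is background-prone and came mostly from sub-cluster 10. Egress genes had a median of 0.54 (-0.09 to 0.81), with S1pr1 2.46-fold (1.89 to 3.24) higher and Lef1 2.22-fold (1.72 to 2.89) higher; it turned to -0.18 with members of at least 50 counts and to -0.01 after background subtraction, and sub-cluster 10 held 37% of S1pr1 counts. Within sub-clusters 3 and 2 both lists lay within the random range, residency at 0.20 (-0.13 to 0.59) and -0.48 (-0.98 to 0.04) and egress at 0.17 (-0.55 to 0.70) and -0.05 (-1.37 to 1.22).

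NF-kB targets had a median of -1.21 (-1.45 to -1.04), with 11 of 14 members at least 2-fold lower in NEVLPcty. Traf1 was 3.93-fold (3.33 to 4.66) lower, Birc3 3.15-fold (2.51 to 3.98) and Nfkbia 1.52-fold (1.41 to 1.63). The level of the list in NEVLPcty still lay above that in CS, at 1.51 (1.17 to 1.80). Within sub-cluster 3 the NEVLPcty against NEVLP2 median was -1.22 (-1.64 to -0.92) and within sub-cluster 2 -1.53 (-1.94 to -1.19).

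Interferon response genes had a median of -1.36 (-1.66 to -1.16), with 12 of 19 members at least 2-fold lower and 0 higher, and against naive the NEVLPcty median was 0.47 (0.24 to 0.81), within the random range. Mx2 was 8.28-fold (3.82 to 21.3) lower, Rtp4 6.07-fold (4.22 to 9.01), Gbp5 3.48-fold (2.77 to 4.41) and Irf1 2.37-fold (1.97 to 2.87), and Samd9, an antiviral factor outside the list, 6.65-fold (3.95 to 12.0). Within sub-clusters 3 and 2 the medians were -1.20 (-1.52 to -0.94) and -1.13 (-1.47 to -0.65).

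Cytokine and chemokine genes had a median of -2.65 (-3.23 to -2.15), with 7 of 9 members at least 2-fold lower; Lta was 3.68-fold (2.42 to 5.81) lower and the background-prone Ccl3 14.5-fold (11.0 to 19.6) lower. Cytotoxicity genes had a median of -0.84 (-1.19 to -0.80), with Gzmk 3.69-fold (3.22 to 4.25) lower, Nkg7 2.91-fold (2.60 to 3.27), and Gzmb 39.7-fold (22.5 to 77.2) and Prf1 5.44-fold (4.30 to 6.97), both background-prone. Sub-cluster 5, which held most of these counts in NEVLP2, had 53 cells there and 5 in NEVLPcty; within sub-cluster 3 the median went the other way, at 0.41 (0.30 to 1.55) and above the random range, within sub-cluster 2 it was -0.16 (-0.33 to 0.06), and by transcripts 0.01. Batf, an AP-1 partner, was 5.42-fold (4.45 to 6.67) lower, Gadd45b 4.95-fold (3.97 to 6.22) and Snx11 12.1-fold (4.95 to 38.2). Ccl1 was 4.98-fold (3.72 to 6.78) lower, but its counts came mostly from 1 cell and the log2 ratio turned to 1.43 without sub-clusters low in Cd3.

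Glucocorticoid response genes had a median of 0.28 (0.07 to 0.44), with Klf9 3.48-fold (2.25 to 5.52) and Tsc22d3 1.71-fold (1.34 to 2.19) higher and Sgk1 2.49-fold (1.73 to 3.64) lower; it turned to -0.04 with doublets removed at the expected rate, and was 0.66 (0.25 to 1.29), above the random range, within sub-cluster 2 and 0.22 (-0.18 to 0.56), within that range, in sub-cluster 3. The antioxidant list was at 0.39 (0.28 to 0.54), with Osgin1 5.58-fold (3.36 to 9.73), Nqo1 7.24-fold (3 to 21.1) and the background-prone Hmox1 6.62-fold (5.81 to 7.56) higher, 72, 62 and 89% of it from sub-cluster 10. MHC class II genes, background-prone, were at -1.25 (-1.43 to -0.99), with Cd74 3.36-fold (2.98 to 3.78) lower. The regulatory list was at -0.34 (-0.52 to 0.09), with Tnfrsf18 2.62-fold (2.24 to 3.08) lower and Tgfb1 1.29-fold (1.15 to 1.44) higher, and 0.23 by transcripts. Within sub-clusters 3 and 2 the antioxidant and regulatory lists lay within the random range. Ribosomal protein genes were at 0.18 (0.14 to 0.19).

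The largest ratios came from few cells. Cma1 (677 counts, at least 288-fold higher) and Mcpt2 (447 counts, at least 190-fold) were each found in 1 NEVLPcty cell of sub-cluster 8, and Mcpt8l2 (40.7-fold, 19.4 to 102) and Mcpt10 (17.8-fold, 10.5 to 32.4) were nearly all from 1 cell; these encode proteases of mast cells and other granulocytes. Mcpt8l2 turned to -1.23 in log2 without sub-clusters low in Cd3. Rhoj (11.5-fold, 5.53 to 27.6) came mostly from sub-cluster 10. Art4 was 9.67-fold (4.38 to 25.2) higher, Dapk1 7.43-fold (3.89 to 15.6) and Susd3 7.41-fold (3.75 to 16.3), the last mostly in sub-cluster 3. Within the random range were cell cycle (0.81, 0.12 to 2.01), glycolysis and hypoxia (0.15, -0.18 to 0.39), cold-inducible (0.02, -0.42 to 0.42), unfolded protein (-0.03, -0.24 to 0.08), mitochondrially encoded (-0.04, -0.11 to 0.00), oxidative phosphorylation (-0.07, -0.16 to 0.00), heat shock (-0.10, -0.22 to 0.04), apoptosis and p53 (-0.11, -0.67 to -0.02) and immediate early genes (-0.20, -0.31 to -0.02). In sub-cluster 2 the apoptosis (-0.90, -1.74 to -0.37), unfolded protein (-0.62, -1.03 to -0.34) and immediate early lists (-0.47, -0.78 to -0.20) lay below it, as did heat shock in sub-cluster 3 (-0.32, -0.53 to -0.13).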

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

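Several clusters were nearly confined to perfused livers. Each of 6 clusters had at least 100 cells in a perfused library and at most 2 cells in naive or CS, and none of them enters the T-like comparisons. Cluster 0, endothelial-like and with Fabp4 and Inhbb among its leading genes, held 1.37% of NEVLP2 cells and 44.4% of NEVLPcty cells. Cluster 8, also endothelial-like, held 3.45 and 8.86%. Cluster 9, hepatocyte-like, held 7.28% of NEVLP2 and 5.07% of NEVLPcty cells. Cluster 21, unnamed, with Selp, Vwf and Sele leading, held 1.08 and 1.82%, and cluster 23, unnamed, with Stc1 and Foxa3 leading, held 1.17 and 1.23%. Cluster 24, neutrophil-like, held 2.12% of NEVLP2 and 0.0689% of NEVLPcty cells. Other clusters were nearly confined to the other livers: cluster 1, endothelial-like, had 3999 of its cells in CS and 6 and 31 in NEVLP2 and NEVLPcty, and cluster 19, monocyte or macrophage-like, had 381 in naive and 3 and 5. With 1 library per group and no batch integration, separation by library is not particular to perfusion. Selp and Sele encode the selectins that activated endothelium shows to leukocytes.

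For the neutrophil-like cells, the test on immune-like cells was chosen only after the result was seen; the test on the filters was not. Neutrophil-like cells were 2.14% of NEVLP2 cells (213 cells, nearly all in cluster 24) and 0.112% of NEVLPcty cells (13 cells), against 2.40% in naive, where cluster 27 held them, and 0.182% in CS. The filters on cells might have removed neutrophils, which hold little RNA, from NEVLPcty alone. Among all deposited barcodes the share with at least 6 neutrophil markers was 89.5-fold higher in NEVLP2 (15.6 to 3578, 81 barcodes against 1). This excludes the filters for barcodes that reach 6 markers. It cannot decide for barcodes with fewer, which include most neutrophil-like cells retained. In NEVLPcty 1 barcode reached 6 markers against 13 such cells, and in NEVLP2 81 against 213. Any selection of barcodes before deposit cannot be examined. More endothelial cells recovered from the NEVLPcty liver could have diluted them, but among immune-like cells the neutrophil-like share was still 10.2-fold higher in NEVLP2 (5.81 to 19.4), which excludes dilution as the whole cause. Fewer neutrophils held in a liver perfused with IL-10 and TGF-β remain possible, as does a loss of neutrophil barcodes with few markers. Differences between 2 animals or 2 cell preparations also remain possible, and 1 library per group cannot separate these.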

How the results depend on the processing

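Of the alternative settings, 11 were chosen before the data were examined, and 5 were added after. Of 874 alternative values for the 55 of 87 list medians outside the random range, 858 kept their direction and 16 did not. Of 1102 values for 80 named gene ratios, 1088 kept it and 14 did not. The genes were picked for extreme ratios and the lists for lying outside the random range, in the same counts. A kept direction was therefore likely in advance. These tallies count direction only, taken as the sign of the log2 ratio, not size or place against random lists. At Leiden resolution 0.5 the T-like cells were the same as in the main analysis, so that setting could change nothing. With T cells taken by transcripts, 45 of 87 list medians were counted as moved and 6 turned direction. No paired analysis was possible because each group has 1 library from a different liver. Values are log2 ratios unless marked as a share, and apart from the sub-cluster sources named below the cause was not tested.

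Taking T cells by transcripts, without clusters, changed the most. Of the cells so taken, 281 of 401 in naive, 101 of 262 in CS, 132 of 462 in NEVLP2 and 101 of 205 in NEVLPcty were T-like in the main analysis. These changes therefore come from a partly different set of cells. T-like shares became 12.2% in naive, 2.5% in CS, 4.63% in NEVLP2 and 1.76% in NEVLPcty. In CS against naive the immediate early list turned to 0.0615, unfolded protein to 0.34, MHC class II to 1.45, Pla2g7 to -0.00898, Enpp3 to -1.23 and Dnajb9 to 0.23. In NEVLP2 against naive the regulatory list turned to -0.0274. In NEVLP2 against CS tissue residency was 0.49, cytotoxicity 2.26 and glucocorticoid response -0.62. In NEVLPcty against NEVLP2 cytotoxicity turned to 0.0137 and the regulatory list to 0.23.

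With each library clustered alone the naive T-like share was 7.56%, tissue residency in CS against naive 0.59, and the immediate early list 0.0338 there and -0.00406 in NEVLP2 against naive. A naive cluster of 103 cells led by T cell markers, with Klra22 and Ly49 genes on top, stayed unnamed and was left out. This setting therefore compares partly different kinds of T-like cells. The cytokine list in CS against naive turned to 0.14, and Ccl1 in NEVLPcty against NEVLP2 to 1.15. Keeping doublets turned the immediate early list in CS against naive to 0.20 and moved glucocorticoid response in NEVLP2 against CS to -0.39. Removing doublets at the expected rate turned glucocorticoid response in NEVLPcty against NEVLP2 to -0.0440. At least 500 genes and 1000 UMIs gave T-like shares of 11.9% in naive and 2.06% in NEVLP2.

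At a mitochondrial maximum of 10%, Enpp3 turned to -0.56 and Ncf1 to -0.0863 in CS against naive, and Mcpt8l2 to -0.62 and Ccl1 to 2.21 in NEVLPcty against NEVLP2. Without sub-clusters low in Cd3 these were -0.60 for Enpp3, -1.23 for Mcpt8l2 and 1.43 for Ccl1, and without those led by other types as well -0.59, -1.01 and 1.66. Sub-cluster 8 held 92.3% of the CS counts of Enpp3 and 99.1% of the NEVLPcty counts of Mcpt8l2, and sub-cluster 9 held 92.6% of the NEVLP2 counts of Ccl1; both are low in Cd3 and were left out in these 2 settings. Why the mitochondrial limit moved the same genes was not tested. The setting without those led by other types also gave a NEVLPcty T-like share of 0.869% and an immediate early median of -0.66 in CS against naive. Without the sub-cluster leading in Ifng, cytotoxicity in NEVLP2 against CS was 0.96.

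The immediate early list was also moved by scaling and depth. In CS against naive it was -0.50 with median ratio scaling, -0.11 thinned, -0.61 without background-prone members and -0.93 with background subtracted. In NEVLP2 against naive these were -0.56, 0.00123, -0.0864 and -0.77, and -0.59 without ribosomal and mitochondrial genes. Thinning to 1000 UMIs also gave 2.36 for cytotoxicity in NEVLP2 against CS, turned tissue residency in NEVLPcty against NEVLP2 to -0.64 and moved the IL-10 and STAT3 list there to -1.18. With members of at least 50 counts the egress list in NEVLPcty against NEVLP2 turned to -0.18, and with background subtracted to -0.00650. Background subtraction also turned the antioxidant list to -0.88 in NEVLP2 against naive and -0.79 against CS.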

Other observations

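NK-like cells of the same livers repeated some of the T-like list medians and not others. There were 174, 333, 439 and 545 NK-like cells in naive, CS, NEVLP2 and NEVLPcty. In NEVLP2 against CS their NF-kB target median was 2.25 (2.03 to 2.60), next to 2.67 in T-like cells, and in NEVLPcty against NEVLP2 their TGF-beta response median was 1.14 (0.68 to 1.36), next to 0.91. Their interferon response median was 0.97 (0.66 to 1.10) in CS against naive, but -0.16 (-0.29 to 0.17) in NEVLP2 against CS, where the T-like median was 1.15. Their immediate early median in CS against naive was 0.61 (0.51 to 0.80), next to the T-like -0.28, whose direction changed with the way T cells were chosen. Their tissue residency and cytotoxicity medians lay within the random range in NEVLP2 against CS, at -0.03 (-0.16 to 0.20) and 0.34 (0.24 to 0.48), and against naive, at 0.01 (-0.06 to 0.22) and 0.22 (0.11 to 0.42), unlike those of T-like cells. Members of the cytotoxicity list went both ways in NK-like cells. Gzmb was at 8321 CPM in NEVLP2 and 1663 in CS, and Prf1 at 9877 and 5749, whereas Gzmm, Klrd1, Ccl5 and Cx3cr1 were lower in NEVLP2. B-like cells (135, 367, 105 and 54) had an NF-kB target median of 1.03 (0.69 to 1.19) in NEVLP2 against CS and a TGF-beta response median of 0.70 (0.43 to 1.21) in NEVLPcty against NEVLP2, with glycolysis genes at 1.40 (1.01 to 1.57) in NEVLP2 against CS. Their cytotoxicity median was 2.24 (1.59 to 2.54) there, for genes that B cells are not known for, so T or NK transcripts may be among their counts.

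The tests of free RNA on the NF-kB target list in NEVLP2 against CS, and the count of cells outside the shared sub-cluster, were chosen only after the result was seen. The test on free RNA first chosen was the subtraction of an estimated background, which left a median of 2.66 but rests on an assumed profile and excludes nothing, so it was replaced. Free RNA from myeloid or endothelial cells could raise these genes in T-like cells, but the level estimated from the markers of other classes was 7.40% of the T-like level in the median member (quartiles 5 to 10.7%), with 84.3% needed. That estimate leaves out NK-like cells and takes unnamed clusters only with the class that leads them. The wider estimate took every other cluster as its own source, unnamed and NK-like ones included, with its share set by its leading genes. The level was then 60.0% (49.1 to 71.1%), and 12 of 14 members lay under the need. This argues against free RNA as the whole cause for the list. It does not exclude free RNA, because each share is a median over leading genes and not an upper limit. The share set by cluster 5, unnamed and with 1815 NEVLP2 cells, was 0.874%, and that by NK-like cluster 11 was 14%, the highest, from leading genes that T cells also carry. A different mix of T-like cells could also do so, since sub-clusters 3 and 5 are nearly confined to perfused livers; within sub-cluster 2 the median was still 2.33 (2.05 to 3.14), which excludes a mix for those cells, but 86.8% of NEVLP2 T-like cells lie outside it and for them the mix cannot be told from a change in state. Within the shared cells the data are in line with NF-kB activity in T cells during perfusion at 37 °C, with 1 animal per group leaving other causes open.

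For the interferon response list in NEVLPcty against NEVLP2, the tests of free RNA and the count of cells outside the shared sub-clusters were again chosen only after the result was seen. Background subtraction, the test first chosen here too, left a median of -1.33 and is not used to exclude. Free RNA from interferon-exposed myeloid cells in NEVLP2 might explain the gap, but its level was 7.57% of the NEVLP2 T-like level in the median member (quartiles 3.23 to 16.6%) from class markers and 27.0% (22.0 to 45.3%) with every other cluster as a source. The need was 61.0%, and 15 of 19 members lay under it in the latter. This argues against free RNA as the whole cause for the list. It does not exclude free RNA, because neither estimate is an upper limit. A mix of sub-clusters might explain it, but within sub-cluster 3 the median was -1.20 (-1.52 to -0.94) and within sub-cluster 2 -1.13 (-1.47 to -0.65), which excludes a mix for the cells they hold, while 50% of NEVLPcty T-like cells lie outside both and cannot be judged. With Ifng also lower, less IFN-γ in the liver perfused with IL-10 and TGF-β is a possible cause, but this was not tested. NK-like cells went both ways: Isg15 was at 518 CPM in NEVLP2 and 146 in NEVLPcty. Gbp5 (385 and 463) and Irf1 (435 and 468), which are inducible by IFN-γ, were not lower in NEVLPcty. In CS against naive the T-like list was higher although Ifng was lower. An exposure particular to the NEVLP2 animal is also possible and untested. Isg15 in T-like cells stood at 677 CPM there and at 75 in NEVLPcty, 103 in CS and 31.9 in naive.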
